A study of Mus musculus with 12 samples.

How the data were processed

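Nuclei were isolated from fresh mouse endometrium following the protocol of the droplet platform (10x Genomics), per the labels, and 12 libraries of total RNA were made, 3 at each of postnatal day 1, 5, 12 and 15. The titles call the samples endometrium epithelium, and how epithelium was taken is not stated. The deposited matrices hold raw UMI counts per gene and cell barcode, 32285 genes in each. The matrix headers name Cell Ranger 6.1.2, while the processing notes list Cell Ranger 2.1.1 with genome build GRCm39. The values were whole numbers of at least 1, and library totals differed. The lowest count per barcode was 500 to 516 UMIs. The filter by which barcodes were called is not stated. No gene positions are given, because the annotation at hand was of another build than GRCm39.

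Of 38850 deposited barcodes, 31821 had at least 500 genes and at most 10% mitochondrial UMIs. Scrublet, as built into scanpy 1.11.5, called 25 doublets, 0.0786% of cells, a share so low that doublets remain in the data. The other 31796 cells were scaled to 10000 counts, log-transformed, reduced to 2000 variable genes and 30 principal components, joined to 15 neighbours and clustered with Leiden (leidenalg 0.10.2) at resolution 1, without batch integration. The planned naming of clusters, by scaled expression relative to other cells, told little because nearly all cells were epithelial. A cluster was therefore named, by a rule chosen after the data were seen, for the class with at least 3 of its own markers in at least 50% of its cells, and stayed unnamed where no class reached this or where its median UMIs lay far under those of its libraries and no marker of the class was among its leading genes. Stromal-like, mesothelial-like and macrophage-like are candidates from marker lists. Tools ran in Python 3.11.15 with anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

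UMIs of epithelial cells were summed per library. Genes were kept by filterByExpr with age as group, 15979 in all, scaled by TMM and tested in edgeR 4.0.16 (R 4.3.3) with robust quasi-likelihood fits over all 12 libraries, which share 1 estimate of the spread. Tests were 2-sided and p-values were adjusted by Benjamini and Hochberg, with calls at adjusted p under 0.05. The SE of a log2 change is its absolute value over the square root of edgeR's F statistic. Where a group holds few UMIs and the change is large, this SE is too small. The median log2 change over all genes was 0.0108 from PND1 to PND5, 0.00749 from PND5 to PND12 and -0.0054 from PND12 to PND15. Gene lists were tested with camera (limma 3.58.1) on log CPM (library-scaled counts) with a prior count of 3, with a preset correlation of 0.01 and, as another setting, an estimated one. P-values were adjusted over lists within a comparison. The 35 lists hold 552 genes, of which Atp5f1a, Atp5f1b, Dnai1 and Spink3 are absent from the files. Of 460 tested list genes, 21 belong to more than 1 list, so the lists are not independent.

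For shares of cells with a UMI, each cell was thinned at random to 8000 UMIs and shallower cells were left out, which kept 27807 epithelial cells. Shares were compared across ages by a permutation F test with 100000 resamples and between 2 ages by an exact 2-sided permutation test, whose smallest p with 3 against 3 libraries is 0.1. Intervals are exact (Clopper-Pearson) at 95%, and a count of 0 allows up to 3 counts. Both cover counting error only. Foxa2-detected and undetected cells of PND12 and PND15 were summed per library after thinning and compared in edgeR with the library as block, with at least 10 Foxa2-detected cells required per library. An interaction term tested whether the difference changed between the ages. Foxa2 itself was left out of that test because it defines the groups.

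Comparisons, tests, lists, marker classes, alternatives and the rule for naming genes were fixed before the data were examined, except where stated. The rule names, per successive step and for the Foxa2 comparison, the 8 largest rises and 8 largest falls among genes past the threshold with an average log2 CPM of at least 5 and no overlap between the ages (for Foxa2, the same sign in every library). Clone-named gene models and nuclear retained or mitochondrial genes are left out there. It adds up to 4 called members of each list with the smallest p, or 2 members where none was called, of which the text gives a part, and a fixed set: Foxa2, Esr1, Pgr, Wnt7a, Hoxa10, Hoxa11, Msx1, Sox9, Lgr5, Axin2, Mki67, Ltf, Gas6, Cited4, Epcam, Krt8, Igf2 and H19. A fold is not given where a group holds 3 counts or fewer. Some genes that the rule names are not reported, though they stay in every count.

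The tests were tested on simulated data, with 50 genes changed at each of 4 folds and a biological coefficient of variation of 2%. Every gene had this same spread, and no effect of the replicate number was simulated. The calls of unchanged genes given here are therefore no false call rate for the real data. From PND1 to PND5, with 15667 genes run, 60%, 84%, 100% and 96% of genes changed 1.2-, 1.5-, 2- and 4-fold were called, and 8 of 15471 unchanged genes. From PND5 to PND12, with 15657 genes run, the shares were 70%, 88%, 90% and 98%, with 8 of 15460. From PND12 to PND15, with 15647 genes run, they were 60%, 84%, 84% and 100%, with 2 of 15449. For the Foxa2 comparison, with 11353 genes run, they were 42%, 94%, 100% and 100%, with 5 of 11153. The changed genes were drawn there only from those with a mean level of at least 5 on the log2 CPM scale. Genes at lower levels were not tried, unlike for the ages, so these shares do not cover them. Replicate libraries were checked for duplication by a chi-square per gene, whose median was 0.604 to 1.06 over 12 pairs against 0.455 expected from counting alone, with Pearson r of log CPM of 0.995 to 0.997.

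Alternatives were DESeq2 1.42.0 size factors and tests, no count filter, a replicate block, leaving out each library, only the libraries compared, other cell filters, doublets kept, Leiden at resolution 0.5 and 2, epithelium defined by UMIs, leaving out Mki67 or Top2a cells or Foxa2 cells, equal cell numbers, thinned sums, and for lists fry. Chosen after the data were seen were a limit of 20% mitochondrial UMIs, leaving out the 5% of cells with the most UMIs, leaving out each library for the lists, and share tests permuted within replicate number. The planned comparisons of stroma were not run, because the minimum of 20 stromal-like cells per library was not met. Unnamed cells entered no gene test.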

Results

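The data were 12 droplet libraries from mouse endometrial epithelium, labelled as isolated nuclei, at postnatal day 1, 5, 12 and 15, written here as PND1, PND5, PND12 and PND15, with 3 libraries per age. The study concerns how the uterine epithelium takes shape after birth, the period in which the gland epithelium separates from the luminal epithelium that lines the cavity. Each library held 1677 to 4274 cell barcodes and between 48373849 and 72955476 unique molecular identifiers (UMIs), with a median of 9673 to 18881 UMIs per barcode. The median share of mitochondrial UMIs per barcode was 5.04% to 5.18% in the PND1 libraries, 4.70% to 4.96% at PND5, 7.19% to 7.34% at PND12 and 7.59% to 7.78% at PND15. Mitochondrial transcripts lie outside the nucleus, so it stays open whether the barcodes hold nuclei or whole cells. Replicate libraries of an age differed by more than sampling noise in all 12 pairs, with a mean chi-square per gene of 1.71 to 6.07, so all 12 libraries were counted. The labels do not say that replicates came from separate animals. All p-values therefore measure the spread between these libraries, which may be technical.

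Epithelial cells made up 30795 of the 31796 cells kept after filtering, with 7652 at PND1, 8985 at PND5, 10044 at PND12 and 4114 at PND15. Their mean share per library was 95.7% ± 1.71 (SD, n = 3) at PND1, 97.2% ± 1.67 at PND5, 98.7% ± 1.77 at PND12 and 94.9% ± 3.13 at PND15. Stromal-like cells, defined by fibroblast collagens and related markers, numbered 56 at PND1, 20 at PND5 and 0 at the later ages. Cluster 7, with 25, 23, 2 and 0 cells at the 4 ages, was named mesothelial-like for its 5 of 5 markers detected. Its leading genes, however, were headed by the fibroblast genes Col3a1, Col1a1 and Dcn and held none of these 5 markers, so the name is weak. At a clustering resolution of 0.5 there was no mesothelial-like cluster and 1 stromal-like cluster of 81, 43, 2 and 0 cells, and without a cell filter 1 stromal-like cluster of 89, 49, 4 and 12 cells. Where stroma ends, and its absence at PND15, so depend on the clustering and the cell filter. Macrophage-like cells numbered 1, 4, 8 and 2. The test of the epithelial share across ages gave p = 0.234 (permutation F test over all libraries), a call that depends on how replicate numbers are treated. The stromal-like share passed (permutation F test, p = 0.00074), from 0.71% ± 0.227 at PND1 and 0.22% ± 0.121 at PND5 to 0 of 1606, 1474 and 1268 cells in the PND15 libraries. A further 860 cells in 3 clusters stayed unnamed, at 3.27% ± 1.74 of cells at PND1, 2.33% ± 1.91 at PND5, 1.23% ± 1.76 at PND12 and 5.10% ± 3.10 at PND15. Of these, 649 formed cluster 3, in which 6 of 7 epithelial markers were detected. It stayed unnamed only by the part of the naming rule on low UMIs. The epithelial shares and their test thus depend on that rule and are not a measure of purity. Epithelial cells of different ages lay mostly in different clusters. Clusters 0 and 1 held 3088 and 3963 cells of PND1, and clusters 8, 9 and 10 held 3187, 3034 and 2151 of PND5. Clusters 14, 15, 16, 17 and 5 held 1663, 2477, 4318, 981 and 566 of PND12, and clusters 4 and 18 held 3100 and 789 of PND15. Cluster 17 also held 167 cells of PND15, and cluster 2 held 517 cells of PND1 and 561 of PND5. Because the sample titles name epithelium, these shares describe the preparations and not the uterus.

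Foxa2, the transcription factor that marks uterine gland epithelium, was near absent at PND1 and PND5 and was detected in a small epithelial fraction from PND12 on. With every cell thinned to 8000 UMIs, the share of epithelial cells with a Foxa2 UMI was 0.109% ± 0.0626 (SD, n = 3 libraries) at PND1, 0.0483% ± 0.055 at PND5, 2.35% ± 0.372 at PND12 and 4.75% ± 0.531 at PND15. The ages differed (permutation F test, p = 0.00012). Neither the step from PND5 to PND12 (2.30 percentage points) nor that from PND12 to PND15 (2.40 points) could pass an exact permutation test of 3 against 3 libraries, whose smallest 2-sided p is 0.1, and both reached it. One PND5 library held 0 of 2514 cells with a Foxa2 UMI, which allows a share of up to 0.119%. Among non-epithelial cells, 0 of 38 held a Foxa2 UMI after thinning. Most of them came from PND1 and PND5 and the count allows up to 7.89%, more than any share above, so they give no background level for PND12 and PND15. The level depends on depth. Without thinning the share was 0.395% ± 0.0938, 0.213% ± 0.0833, 4.25% ± 0.355 and 7.76% ± 1.24 at the 4 ages, and with cells thinned to 4000 UMIs 0.0546% ± 0.0473, 0.0455% ± 0.0394, 1.05% ± 0.17 and 2.68% ± 0.587. The median depth before thinning was 13250 UMIs in those 38 cells and 15950 to 24360 in the epithelial cells of the libraries. Epithelial cells were also clustered again, into subclusters. Subcluster 11, with 663 of its 667 cells from PND15, had gland epithelium as its best-scoring marker class (3.24). It held 14.6% to 16.99% of epithelial cells in the PND15 libraries. Without thinning, 44.1% of its cells had a Foxa2 UMI and 31.2% a Cxcl15 UMI. Subcluster 7, nearly all PND12 cells, had the same best class at a score of 0.0561. The Foxa2-detected share is thus not a share of gland-like cells.

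Epithelial cells with a UMI of a proliferation gene became fewer over the same period. After thinning, a UMI of the proliferation genes Mki67 or Top2a was found in 62.1% ± 1.65 of epithelial cells at PND1, 61.1% ± 2.22 at PND5, 34.2% ± 4.32 at PND12 and 13.5% ± 0.838 at PND15 (SD, n = 3 libraries). The ages differed (permutation F test, p = 0.00038). The falls of -26.9 points from PND5 to PND12 and -20.6 points from PND12 to PND15 separated all libraries (exact permutation test, p = 0.1, the smallest possible). From PND1 to PND5 the difference of -0.94 points lay within the spread between libraries (exact permutation test, p = 0.6). Without thinning the shares were 72.4% ± 1.15, 66.5% ± 1.72, 40.1% ± 1.91 and 29.1% ± 1.71 at the 4 ages, and the change from PND1 to PND5, -5.86 points, separated all libraries (exact permutation test, p = 0.1, the smallest possible). With cells thinned to 4000 UMIs the shares were 48.2% ± 1.03, 46.0% ± 2.19, 23.2% ± 0.725 and 8.90% ± 0.92. Among 38 non-epithelial cells, 18 held such a UMI, more than the shares at PND12 and PND15, so these cells set no background level. The thinning left out 1162 epithelial cells of PND12 replicate 1, more than in any other library.

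**Figure D1:**
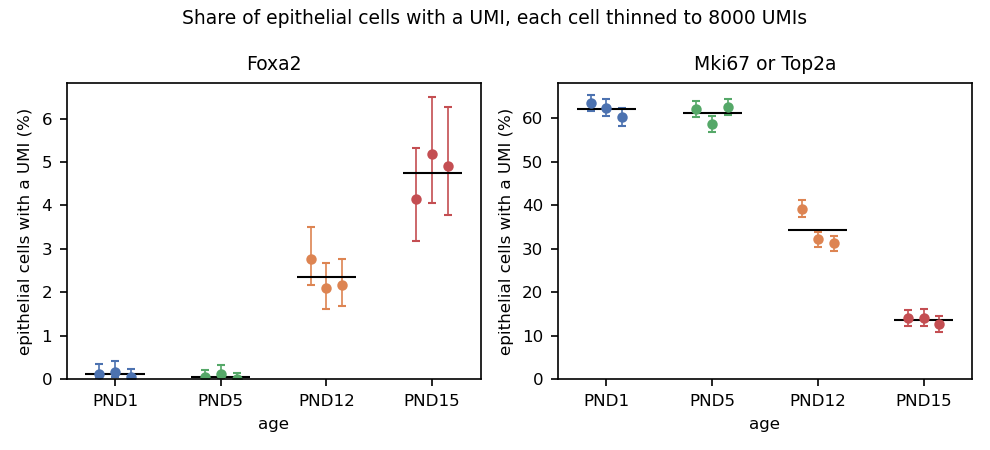
Share of epithelial cells (%, vertical axis) with a Foxa2 UMI (left) or a Mki67 or Top2a UMI (right) at each age (horizontal axis), after thinning every cell to 8000 UMIs. Points are libraries with exact 95% binomial intervals, which cover counting error only, and black lines are means: Foxa2 rose from 0.0483% at PND5 to 4.75% at PND15, and Mki67 or Top2a fell from 61.1% to 13.5%.

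The ages differed in nearly the whole epithelial transcriptome. Summed epithelial counts held 41419643 to 71210454 UMIs per library, and replicates of an age differed little, with a common biological coefficient of variation of 2.16%. Of 15979 genes tested, 15037 differed among the 4 ages (edgeR quasi-likelihood test, adjusted p under 0.05). Between the successive ages, 61.9%, 75.9% and 72.5% of genes showed no overlap between the 3 libraries of each age, where chance gives 10%. With so small a spread many called changes are small, and the counts of at least 2-fold changes are given beside all calls. Sums of Hoxa10 and Hoxa11, patterning genes of the uterus that are strong in its stroma, held at most 1 UMI per library, too few to test.

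From PND1 to PND5 the receptor genes Esr1 and Pgr rose and the imprinted genes Meg3 and Cdkn1c fell. Calb1, which encodes a cytosolic calcium-binding protein, rose by 4.72 ± 0.08 on the log2 scale (SE, n = 3 libraries per age), and Aldh1a1, an enzyme that makes retinoic acid, by 3.70 ± 0.08. The oestrogen receptor gene Esr1 rose by 2.79 ± 0.05 and the progesterone receptor gene Pgr by 1.74 ± 0.02. Further large rises were those of Sprr2f (3.56 ± 0.10), the tetraspanin Tspan8 (3.34 ± 0.03), Thrsp (3.15 ± 0.03), the zinc importer Slc39a4 (2.83 ± 0.06) and the secreted phospholipase Pla2g10 (2.68 ± 0.04). In the other direction, the tubulin-binding Stmn2 changed by -2.79 ± 0.03, the matricellular Sparc by -2.11 ± 0.03, the imprinted non-coding RNA Meg3 by -1.84 ± 0.06 and the imprinted cell cycle inhibitor Cdkn1c by -1.41 ± 0.02. Mfap2 (-1.27 ± 0.03), Fstl1 (-1.13 ± 0.02), Cald1 (-1.09 ± 0.03) and Amotl2 (-1.05 ± 0.04) also fell. The 8 largest rises and 8 largest falls were taken among genes past edgeR's test, with an average log2 CPM of at least 5. No overlap between libraries was also required, and their adjusted p was at most 8.3e-09.

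Gene groups moved with them. Among imprinted growth genes, 3 of 23 rose, 18 fell and 2 did not pass the test (3 and 18 adjusted over the list alone), with Dlk1 at -4.19 ± 0.09, Igf2 at -3.64 ± 0.38 and H19 at -3.53 ± 0.13. The list lay below other genes (camera adjusted p = 9.04e-07, and adjusted p = 0.00957 with an estimated correlation). H19 was also among the leading genes of the mesothelial-like cluster 7, and stromal-like cells went from 56 to 20 in this step. RNA carried over from such cells was not corrected for, and its part in these falls was not tested. Of the fetal RNA-binding and chromatin genes, 3 of 20 rose, 14 fell and 3 did not pass the test (3 and 15 adjusted over the list alone), among them Igf2bp3 (-1.39) and Igf2bp1 (-1.57). That list was also down (camera adjusted p = 0.00277, and adjusted p = 0.0722 with an estimated correlation). Steroid hormone receptor and oestrogen response genes were up, as 12 of 19 rose, 5 fell and 2 did not pass the test (12 and 5 adjusted over the list alone), with camera adjusted p = 0.00820, and adjusted p = 0.0821 with an estimated correlation. Luminal epithelium genes such as Lpar3 (2.19) and Met (0.55) were up as well: 10 of 14 rose, 2 fell and 2 did not pass the test (10 and 2 adjusted over the list alone), with camera adjusted p = 0.00456, and adjusted p = 0.0821 with an estimated correlation. Antigen presentation and interferon response genes, led by Psmb8 (1.22) and H2-K1 (0.59), gave 13 of 21 rose, 2 fell and 6 did not pass the test (14 and 2 adjusted over the list alone), with camera adjusted p = 0.00277, and adjusted p = 0.225 with an estimated correlation. For innate defence and secretion, 13 of 24 rose, 4 fell and 7 did not pass the test (13 and 4 adjusted over the list alone), with Cfb at 1.45 and Ltf at 2.08 rising and Nfkbia at -0.56 falling (camera adjusted p = 0.0168, and adjusted p = 0.0821 with an estimated correlation).

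Metabolic and structural groups rose slightly. For oxidative phosphorylation and glycolysis, 16 of 20 rose, 1 fell and 3 did not pass the test (16 and 1 adjusted over the list alone), with Aldoa at 0.55 and Hk1 at 0.80 (camera adjusted p = 0.000366, and adjusted p = 0.228 with an estimated correlation). For lipid and cholesterol synthesis, 13 of 20 rose, 1 fell and 6 did not pass the test (13 and 1 adjusted over the list alone), with Scd1 at 1.10 (camera adjusted p = 0.00485, and adjusted p = 0.0821 with an estimated correlation). Epithelial keratins and junctions gave 12 of 15 rose, 1 fell and 2 did not pass the test (12 and 1 adjusted over the list alone), with Cdh1 at 0.34 and Krt8 at 0.26 (camera adjusted p = 0.00771, and adjusted p = 0.225 with an estimated correlation). Of the other cell types, mesothelial genes fell in 3 of 4 measured members (3 adjusted over the list alone), with Cdh2 at -0.92 and Upk3b at -0.94 (camera adjusted p = 0.0129, and adjusted p = 0.209 with an estimated correlation). The median change was -0.75 for 9 stromal genes, -0.92 for 6 smooth muscle genes, 0.18 for 17 stress genes and 0.02 for 10 nuclear and mitochondrial RNAs, none of these lists past camera. Of 26 S phase genes 6 rose and 6 fell (6 and 6 adjusted over the list alone), and of 28 G2 and mitosis genes 10 rose and 2 fell (10 and 2 adjusted over the list alone), without either list passing camera (adjusted p = 0.817 and 0.340). Mki67 itself did not pass (0.16 ± 0.06, edgeR adjusted p = 0.0511), but did without PND5 replicate 2 (0.19), PND15 replicate 2 (0.14) or PND15 replicate 3 (0.14).

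Neither the uterine gland list nor the canonical Wnt list passed camera (adjusted p = 0.210 and 0.587). Foxa2 did not pass the test (-0.46 ± 0.78, edgeR adjusted p = 0.641). Of 10 measured uterine gland genes, 3 rose and 2 fell (3 and 2 adjusted over the list alone). Lgr5, a receptor of the Wnt pathway and a stem cell marker, was at 1.08 ± 0.02 and Sox9 at -0.28 ± 0.04. Of the 2 gland genes known from the study, Cited4 rose (1.36 ± 0.08) and Gas6 fell (-1.24 ± 0.26). That pair was chosen from knowledge of the study and is not independent evidence. Among 24 canonical Wnt genes 8 rose and 9 fell (8 and 9 adjusted over the list alone), with Wnt10a at -3.11 ± 0.15 and the target Axin2 not past the test at -0.06 ± 0.06 (edgeR adjusted p = 0.452), though it passed without PND5 replicate 2 (-0.13). Wnt7a, a luminal Wnt ligand, moved by -0.10 and the homeobox gene Msx1 rose by 0.28, and Epcam by 0.14. In all, 9258 genes passed, 4963 up and 4295 down, of which 631 and 738 changed at least 2-fold. Without cells carrying a Mki67 or Top2a UMI, which removes most cells at these ages, 5136 passed.

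Between PND5 and PND12 Foxa2 appeared. It rose by 5.46 ± 0.34 on the log2 scale (SE, n = 3 libraries per age), from 21 UMIs over all PND5 epithelial cells to 784 at PND12. Fxyd4, a regulator of the sodium-potassium pump, rose by 3.67 ± 0.02, the carbonyl reductase Cbr2 by 3.56 ± 0.03, and the tight junction claudin Cldn10 by 3.32 ± 0.04. Cited4 rose by 3.23 ± 0.04, the endocytic receptor Lrp2 by 3.22 ± 0.04 and Calb1 by 3.06 ± 0.05. Fam189a2 (3.42 ± 0.06) and Hdc (3.16 ± 0.04), the enzyme that makes histamine, followed. The largest falls were those of Sparc (-4.54 ± 0.04), the interferon-induced chemokine Cxcl10 (-4.32 ± 0.08), Fstl1 (-2.53 ± 0.03), Meg3 (-2.38 ± 0.09), the retinoic acid-binding Crabp1 (-2.34 ± 0.02), the homeobox gene Meis2 (-2.25 ± 0.04), fibronectin Fn1 (-2.22 ± 0.04) and Cldn6 (-2.13 ± 0.03). Taken by the same rule among genes past edgeR's test, the 8 largest rises and 8 largest falls had an adjusted p of at most 8.1e-09.

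Cell cycle genes fell as a body. For S phase and DNA replication, 0 of 26 rose, 26 fell and 0 did not pass the test (0 and 26 adjusted over the list alone), with Mcm4 at -0.94 ± 0.03 and Rrm2 at -1.15 ± 0.04 (camera adjusted p = 8.10e-11, and adjusted p = 0.0394 with an estimated correlation). For G2 and mitosis, 0 of 28 rose, 28 fell and 0 did not pass the test (0 and 28 adjusted over the list alone), with Ccna2 at -1.06 ± 0.03 and Ect2 at -1.10 ± 0.03 (camera adjusted p = 8.81e-11, and adjusted p = 0.361 with an estimated correlation). Mki67 changed by -0.86 ± 0.06. Among cells with at least 1000 genes and at most 5% mitochondrial UMIs, of which PND12 libraries held 35 to 62, Ccna2, Ect2 and Mki67 instead changed by 0.60, 0.54 and 0.77. Imprinted growth genes continued down: 5 of 23 rose, 15 fell and 3 did not pass the test (5 and 16 adjusted over the list alone), with Nnat at -3.83 ± 0.07 and Cdkn1c at -1.13 ± 0.02 (camera adjusted p = 0.00255, and adjusted p = 0.0417 with an estimated correlation). Lists of other cell types had lower medians in the same step, at -0.58 for 9 stromal genes (3 rose and 4 fell) and -0.92 for 4 mesothelial genes (1 rose and 3 fell), without passing camera (adjusted p = 0.963 and 0.315), and stromal-like cells went from 20 to 0, or from 43 to 2 at the clustering resolution of 0.5. Fetal RNA-binding and chromatin genes fell as well: 1 of 20 rose, 18 fell and 1 did not pass the test (1 and 18 adjusted over the list alone), with the growth factors Mdk at -1.82 ± 0.02 and Ptn at -0.96 ± 0.02 (camera adjusted p = 6.95e-08, and adjusted p = 0.00773 with an estimated correlation). For lipid and cholesterol synthesis, 3 of 20 rose, 17 fell and 0 did not pass the test (3 and 17 adjusted over the list alone), with Hmgcs1, an enzyme of cholesterol synthesis, at -1.16 ± 0.02 (camera adjusted p = 0.000204, and adjusted p = 0.0394 with an estimated correlation).

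On the rising side, antigen presentation and interferon response genes gave 15 of 21 rose, 3 fell and 3 did not pass the test (15 and 3 adjusted over the list alone), with Ifitm3 at 0.51 rising and Irf1 at -1.32 falling (camera adjusted p = 0.00255, and adjusted p = 0.361 with an estimated correlation). Nuclear retained and mitochondrial RNAs rose beside them: 9 of 10 rose, 1 fell and 0 did not pass the test (9 and 1 adjusted over the list alone), with mt-Co1 at 0.72 and mt-Nd1 at 0.73 (camera adjusted p = 0.000255, and adjusted p = 0.361 with an estimated correlation), in the same step in which the mitochondrial share of barcodes rose. Of the uterine gland genes, 8 of 10 rose, 2 fell and 0 did not pass the test (8 and 2 adjusted over the list alone), with Lgr5 at 0.35, Aldh1a1 at 1.05 and the sulfotransferase Sult1d1 at 5.65 rising and Sox9 at -0.87 falling, but the list did not pass camera (adjusted p = 0.0786). Steroid hormone receptor and response genes rose in 11 of 19 and fell in 5 (11 and 5 adjusted over the list alone), Esr1 by 2.07 and Pgr by 0.23, also short of camera's threshold (adjusted p = 0.0786). Cell cycle inhibitors fell in 9 of 14 and rose in 3 (9 and 3 adjusted over the list alone), with Cdkn1a at -1.92, with camera adjusted p = 0.0827. Innate defence and secretion genes rose in 11 of 24 and fell in 8 (11 and 8 adjusted over the list alone, camera adjusted p = 0.902). Stress genes moved both ways (6 rose and 6 fell of 17, 6 and 6 adjusted over the list alone, camera adjusted p = 0.937).

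The fixed genes filled in this picture. Ltf, an oestrogen-induced secretory gene, rose by 2.07 and Msx1 by 0.18, while Wnt7a moved by -0.19, Axin2 by -0.19, H19 by -3.10, Epcam by -0.06 and Krt8 by 0.17. Axin2 did not pass without PND5 replicate 2 (-0.11, adjusted p = 0.0567) or PND12 replicate 1 (-0.18, adjusted p = 0.0552), nor did Epcam (-0.04, adjusted p = 0.103 and -0.05, adjusted p = 0.0636). Gas6 did not pass (log2 change 0.71 ± 0.29, edgeR adjusted p = 0.0520), and among epithelial cells without a Foxa2 UMI its change was -0.32. Among all epithelial cells it passed without PND12 replicate 3 (0.85), PND15 replicate 1 (0.71) or PND15 replicate 2 (0.71). With at least 1000 genes and at most 5% mitochondrial UMIs required per cell, Axin2, Epcam and Krt8 turned direction, to 1.05, 0.24 and -0.02. In all, 11876 genes passed, 6039 up and 5837 down, of which 1182 and 1170 changed at least 2-fold. Under the stricter cell filter 2428 passed, 1129 up and 1299 down.

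From PND12 to PND15 immediate early genes rose together, and S phase, retinoid and lipid genes fell. Socs3, an inhibitor of cytokine signalling, rose by 3.03 ± 0.05 on the log2 scale (SE, n = 3 libraries per age), Cited4 by 2.50 ± 0.03, the small GTPase Rasd1 by 2.49 ± 0.06, the calcium-binding S100g by 2.35 ± 0.06 and Cldn10 by 2.32 ± 0.03. Sbno2 (2.31 ± 0.04), the transcription factor Cebpd (2.05 ± 0.02) and Nfkbiz (2.02 ± 0.03) followed. The insulin-like growth factor-binding Igfbp2 fell most among these, at -7.16 ± 0.14, from 6085 UMIs over the PND12 libraries to 29. Counting error on 29 UMIs is larger than this SE. Crabp1 changed by -4.30 ± 0.05, and the growth factor Mdk by -4.13 ± 0.04. Ecrg4 changed by -3.73 ± 0.08, Sparc by -3.57 ± 0.16, the actin-bundling Fscn1 by -3.01 ± 0.08 and the prostaglandin synthase Ptgds by -2.79 ± 0.04. Taken by the same rule among genes past edgeR's test, the 8 largest rises and 8 largest falls had an adjusted p of at most 4.13e-10.

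All 17 immediate early and dissociation stress genes rose (17 adjusted over the list alone), with Fosb at 1.49 ± 0.02 and Jun at 1.11 ± 0.02 (camera adjusted p = 7.22e-11, and adjusted p = 0.0428 with an estimated correlation). Nuclear retained and mitochondrial RNAs rose beside them in 9 of 10 (9 adjusted over the list alone), by a median of 0.18, with mt-Co1 at 0.30 (camera adjusted p = 0.00494, and adjusted p = 0.298 with an estimated correlation). Epithelial transcription factors gave 17 of 26 rose, 5 fell and 4 did not pass the test (17 and 6 adjusted over the list alone), with Cebpd at 2.05 and Stat3 at 1.06 (camera adjusted p = 0.00500, and adjusted p = 0.218 with an estimated correlation). For keratins and junctions, 11 of 15 rose, 2 fell and 2 did not pass the test (11 and 2 adjusted over the list alone), with Cldn3 at 0.74 and Krt19 at 0.54 (camera adjusted p = 0.02, and adjusted p = 0.245 with an estimated correlation). The cell cycle lists fell further. All 26 S phase genes fell (26 adjusted over the list alone), with Rrm1 at -1.10 and Rrm2 at -2.35 (camera adjusted p = 6.49e-13, and adjusted p = 0.0428 with an estimated correlation). All 28 G2 and mitosis genes fell (28 adjusted over the list alone), with Ccna2 at -2.02 and Birc5 at -1.83 (camera adjusted p = 1.21e-13, and adjusted p = 0.227 with an estimated correlation).

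Retinoid metabolism and response genes fell together, as 2 of 17 rose, 12 fell and 3 did not pass the test (2 and 12 adjusted over the list alone), with camera adjusted p = 0.00247, and adjusted p = 0.0428 with an estimated correlation. Besides Crabp1, Aldh1a3 changed by -4.45 ± 0.06 and the retinol transporter gene Stra6 by -1.84 ± 0.06. Aldh1a1, which had risen until PND12, changed by -2.28 ± 0.06. For lipid and cholesterol synthesis, 4 of 20 rose, 15 fell and 1 did not pass the test (4 and 15 adjusted over the list alone), with Hmgcs1 at -1.35 and Fdps at -0.88 (camera adjusted p = 0.000617, and adjusted p = 0.0428 with an estimated correlation). For fetal RNA-binding and chromatin genes, 4 of 20 rose, 13 fell and 3 did not pass the test (4 and 13 adjusted over the list alone), with Ptn at -2.43 and Mdk at -4.13 (camera adjusted p = 0.00656, and adjusted p = 0.0597 with an estimated correlation). Mesothelial genes fell in all 4 measured members (4 adjusted over the list alone), with Cdh2 at -1.88 (camera adjusted p = 0.0318, and adjusted p = 0.227 with an estimated correlation). Canonical Wnt genes fell in 14 of 24 and rose in 5 (15 and 5 adjusted over the list alone). Porcn rose, at 1.31, against Lgr5 at -0.65, Tcf7 at -1.52 and Lef1 at -3.27, without passing camera (adjusted p = 0.0788).

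Foxa2 rose by 1.06 ± 0.15 and Gas6 by 1.70 ± 0.23, whereas among epithelial cells without a Foxa2 UMI Gas6 changed by -0.62. Esr1 rose by 0.40, Ltf by 0.44, Msx1 by 0.22 and Krt8 by 0.06, which did not pass without PND12 replicate 2 (0.05, adjusted p = 0.0560). Of the uterine gland genes, 3 of 10 rose, 4 fell and 3 did not pass the test (3 and 4 adjusted over the list alone), with a median of -0.01 (camera adjusted p = 0.563). Pgr (-0.42), Wnt7a (-0.80), Sox9 (-0.94), Axin2 (-1.46), Mki67 (-1.77) and Epcam (-0.10) fell. Igf2 was at 1 UMI at each of these ages, and H19 at 8 and 5. In all, 11159 genes passed edgeR's test, 5540 up and 5619 down, of which 927 and 1327 changed at least 2-fold. The filter of at least 1000 genes and at most 5% mitochondrial UMIs left 2 to 12 epithelial cells per PND15 library and 819 calls, 252 up and 567 down, with Krt8 at -0.18.

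Over the whole interval, from PND1 to PND15, 13755 of 15979 genes passed edgeR's test, 6938 up and 6817 down, of which 2575 and 2804 changed at least 2-fold. Esr1 stood at 3.30 ± 0.144 library-scaled counts (CPM, mean ± SD, n = 3) at PND1, 22.9 ± 0.690 at PND5, 96.1 ± 2.76 at PND12 and 127 ± 1.78 at PND15. Pgr peaked at PND12, with 335 ± 7.39 CPM against 85.7 ± 0.662 at PND1. Sox9 went from 97.7 ± 2.32 to 23.0 ± 1.69 CPM. Of the 35 gene lists, 12 passed camera, 7 up and 5 down, and 3 also with an estimated correlation. S phase genes were among these 3 (26 of 26 fell, 26 adjusted over the list alone, camera adjusted p = 3.19e-10, and adjusted p = 0.0465 with an estimated correlation). Imprinted growth genes were another (19 of 23 fell, 19 adjusted over the list alone, camera adjusted p = 0.000199, and adjusted p = 0.0298 with an estimated correlation). Fetal RNA-binding and chromatin genes were the last (19 of 20 fell, 19 adjusted over the list alone, camera adjusted p = 1.08e-06, and adjusted p = 0.0137 with an estimated correlation). Lists of other cell types had lower medians over the same interval, at -1.92 for 9 stromal genes (6 fell), -3.26 for 4 mesothelial genes (3 fell) and -3.54 for 2 lymphatic endothelial genes (both fell), without passing camera (adjusted p of 0.165 to 0.413). Stress genes rose in 16 of 17 (16 adjusted over the list alone, camera adjusted p = 1.46e-05, and adjusted p = 0.162 with an estimated correlation). Nuclear and mitochondrial RNAs rose in 10 of 10 (10 adjusted over the list alone, camera adjusted p = 0.000199, and adjusted p = 0.264 with an estimated correlation). With at least 1000 genes and at most 5% mitochondrial UMIs per cell, 2116 genes passed, 823 up and 1293 down.

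**Figure D2:**
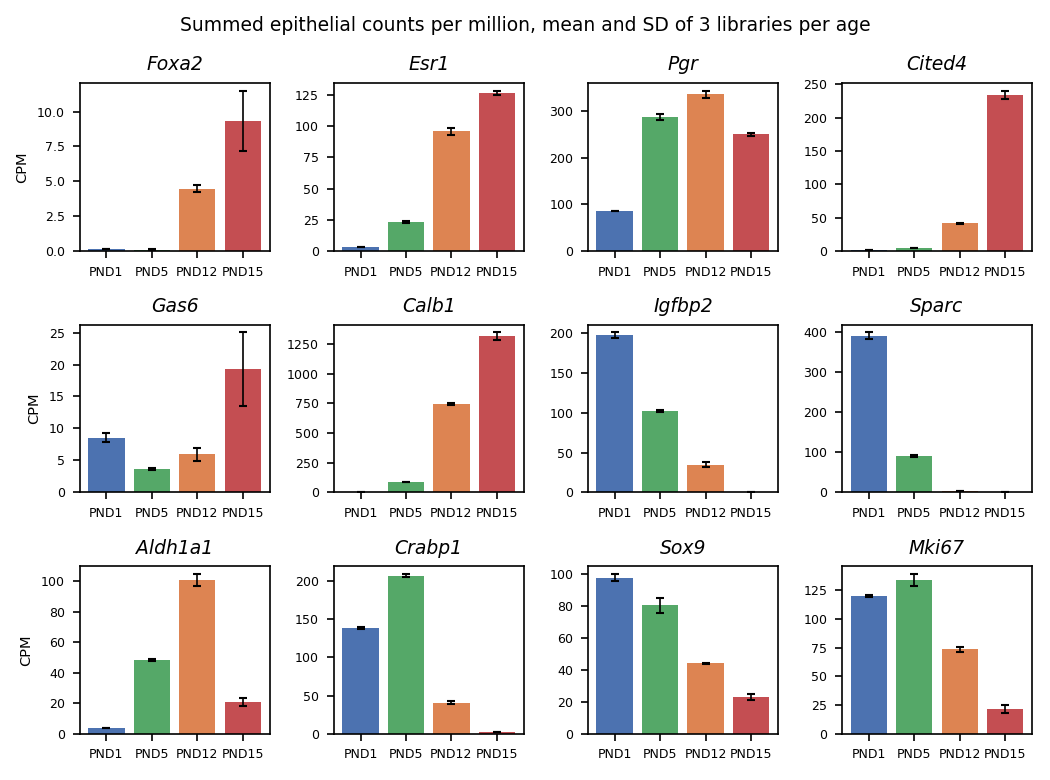
Level of 12 genes in summed epithelial counts (CPM, library-scaled counts, vertical axis) at each age (horizontal axis). Bars are means and error bars SD of 3 libraries: Esr1 rose from 3.30 to 127 CPM and Igfbp2 fell from 197 to 0.239 CPM between PND1 and PND15.

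**Figure D3:**
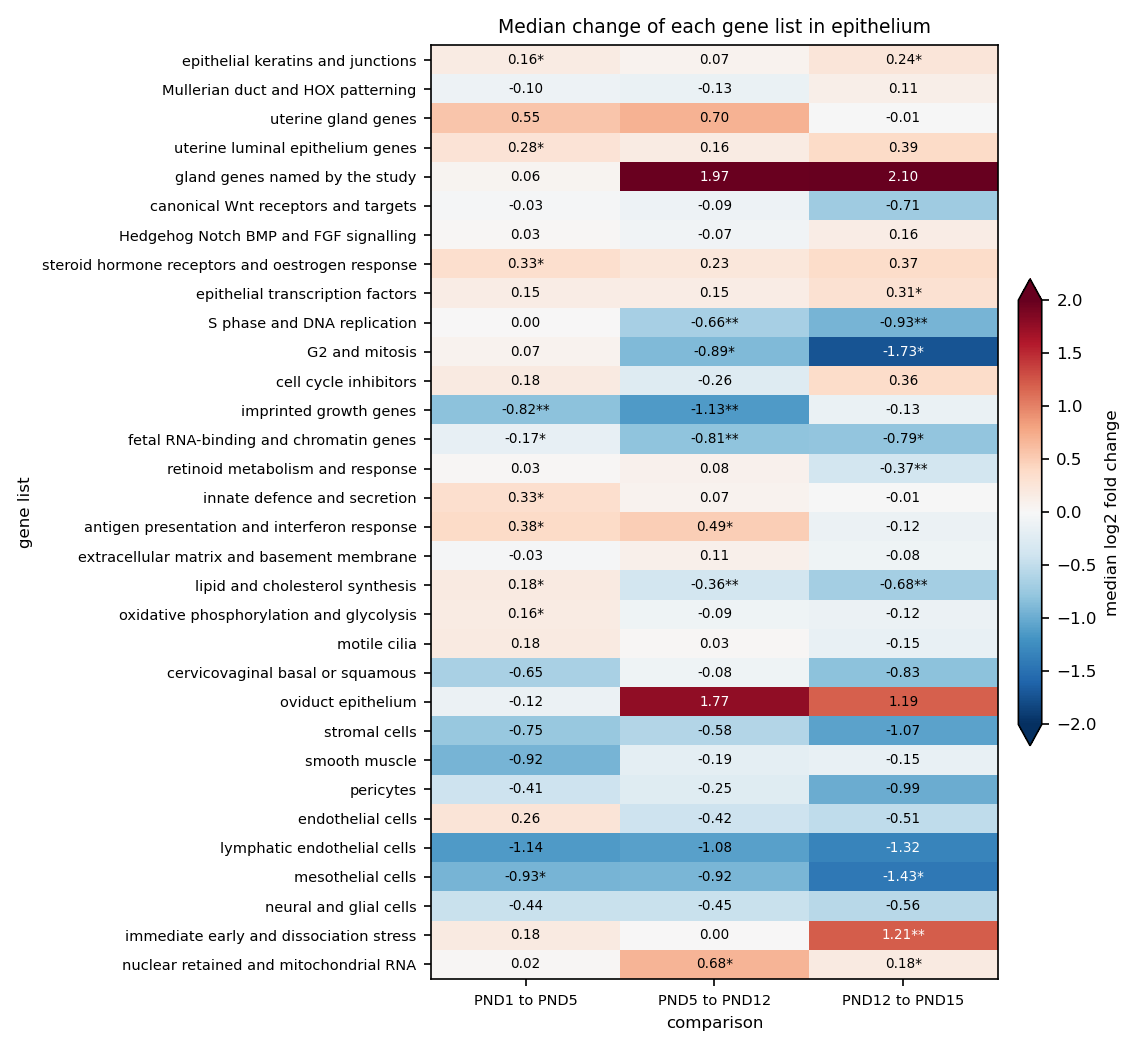
Median log2 fold change (colour and number) of each fixed gene list (vertical axis) between successive ages (horizontal axis), with the macrophage, other leukocyte and erythroid lists left out for their 1 or 2 measured genes. One star marks lists past camera with a preset correlation and a pair of stars those also past it with an estimated correlation, as for the stress list from PND12 to PND15, whose median was 1.21.

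Further lists did not pass camera in any successive step, and their medians from PND1 to PND5, PND5 to PND12 and PND12 to PND15 were as follows. Mullerian duct and HOX patterning genes (11 measured) stood at -0.10, -0.13 and 0.11. Hedgehog, Notch, BMP and FGF signalling genes (37) stood at 0.03, -0.07 and 0.16, and extracellular matrix and basement membrane genes (26) at -0.03, 0.11 and -0.08. Genes of motile cilia (10) were at 0.18, 0.03 and -0.15, of cervicovaginal basal or squamous epithelium (8) at -0.65, -0.08 and -0.83 and of oviduct epithelium (4) at -0.12, 1.77 and 1.19. Among other cell types, stromal genes (9) were at -0.75, -0.58 and -1.07 and smooth muscle genes (6) at -0.92, -0.19 and -0.15. Pericyte genes (3) were at -0.41, -0.25 and -0.99 and endothelial genes (7) at 0.26, -0.42 and -0.51. Lymphatic endothelial genes (2) were at -1.14, -1.08 and -1.32 and neural and glial genes (4) at -0.44, -0.45 and -0.56. Macrophages and other leukocytes kept 1 measured gene each, at 0.24, -0.11 and 0.50 and at 0.08, -1.74 and -2.47, and erythroid cells 2, at 1.05, -0.71 and 3.63. The pair of gland genes known from the study had medians of 0.06, 1.97 and 2.101. Lists that passed in another step did not pass in these: from PND12 to PND15 antigen presentation (-0.12), innate defence (-0.01), steroid hormone receptor (0.37), luminal (0.39), imprinted (-0.13) and oxidative phosphorylation genes (-0.12). From PND5 to PND12 they were luminal (0.16), oxidative phosphorylation (-0.09), keratin and junction (0.07), epithelial transcription factor (0.15) and retinoid genes (0.08), and from PND1 to PND5 epithelial transcription factor (0.15) and retinoid genes (0.03) (medians, camera adjusted p of 0.129 to 0.937). Over the 3 successive steps and the whole interval, 39 list calls passed camera and 12 did so with an estimated correlation.

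Within the epithelium of PND12 and PND15, cells with a Foxa2 UMI differed widely from those without. Each library served as its own control, with 60 to 70 Foxa2-detected cells per library, each thinned to 8000 UMIs. Secreted Egfl6 was higher by 3.01 ± 0.12 on the log2 scale (SE, n = 6 libraries), the transcription factors Mitf and Sox9 by 2.47 ± 0.09 and 2.18 ± 0.11, Wfdc15b by 2.44 ± 0.06. The retinol dehydrogenase Rdh10 was higher by 2.42 ± 0.10, the non-coding RNA Snhg11 by 2.31 ± 0.10, the cyclin Ccnd1 by 2.21 ± 0.06 and the glutathione transferase Gstm7 by 2.20 ± 0.04. Lower were the Wnt ligand Wnt4, at -4.49 ± 0.31, Tubb2b, at -4.25 ± 0.28, the protease Klk10, at -4.02 ± 0.31, and the glutamate transporter Slc1a3, at -4.01 ± 0.25. So were the ectonucleotidase Nt5e, at -3.71 ± 0.28, Sfn, at -3.55 ± 0.27, and Map1b, at -3.50 ± 0.20. Without PND12 replicate 3 Nt5e stood at -6.81. The 8 highest and 8 lowest were taken among genes past edgeR's test, with an average log2 CPM of at least 5. The same sign in all 6 libraries was also required, and their adjusted p was at most 5.84e-28. Wnt4, Klk10 and Tubb2b rest on 6, 7 and 8 UMIs in the Foxa2-detected cells. Counting error on so few UMIs is alone larger than the SE given for these genes.

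Gland genes were higher and luminal genes lower. Of the uterine gland list, 4 of 7 were higher, 1 were lower and 2 did not pass the test (4 and 1 adjusted over the list alone): Cxcl15 at 4.96 ± 0.15, Sox9, and Aldh1a1 at 2.17 ± 0.11 were higher and Wfdc2 at -1.35 ± 0.02 was lower (camera adjusted p = 0.00385, and adjusted p = 0.119 with an estimated correlation). The luminal list gave 3 of 13 were higher, 8 were lower and 2 did not pass the test (3 and 8 adjusted over the list alone), with Wnt7a at -2.58 ± 0.15, but Ihh, a Hedgehog ligand placed in that list, at 3.64 ± 0.12 (camera adjusted p = 0.0322, and adjusted p = 0.136 with an estimated correlation). Gas6 and Cited4, known from the study and so not independent evidence, were at 4.61 ± 0.15 and 1.24 ± 0.08 (camera adjusted p = 0.000666, and adjusted p = 0.119 with an estimated correlation). Canonical Wnt genes were higher in 12 of 20 and lower in 3 (12 and 4 adjusted over the list alone), with Sp5 at 4.39 ± 0.17, Wif1 at 4.86 ± 0.30 and Axin2 at 1.91 ± 0.21 (camera adjusted p = 0.000152, and adjusted p = 0.119 with an estimated correlation). Lgr5 did not pass the test (-0.07 ± 0.09, edgeR adjusted p = 0.598), and without thinning it turned direction, to 0.51. Keratins and junctions gave 1 of 15 were higher, 12 were lower and 2 did not pass the test (1 and 13 adjusted over the list alone), with Krt19 at -1.78 ± 0.04 and Krt8 at -0.78 ± 0.03 (camera adjusted p = 9.32e-06, and adjusted p = 0.119 with an estimated correlation).

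Cell cycle genes were also higher. For G2 and mitosis, 25 of 28 were higher, 0 were lower and 3 did not pass the test (25 and 0 adjusted over the list alone), with Top2a at 1.15 ± 0.10 and Mki67 at 1.37 ± 0.13 (camera adjusted p = 4.81e-11, and adjusted p = 0.119 with an estimated correlation). For S phase, 14 of 26 were higher, 0 were lower and 12 did not pass the test (14 and 0 adjusted over the list alone), with Tyms at 0.68 and Mcm5 at 0.90 (camera adjusted p = 1.50e-06, and adjusted p = 0.119 with an estimated correlation). Stress genes were lower in 16 of 17 (17 adjusted over the list alone), with Hspb1 at -2.36 and Junb at -0.996 (camera adjusted p = 7.32e-10, and adjusted p = 0.119 with an estimated correlation). Innate defence genes were lower in 9 of 20 and higher in 0 (11 and 0 adjusted over the list alone, camera adjusted p = 0.000558, and adjusted p = 0.119 with an estimated correlation). Antigen presentation genes were lower and higher in 9 of 18 and 0 (10 and 0 adjusted over the list alone, camera adjusted p = 0.0110, and adjusted p = 0.119 with an estimated correlation). Hedgehog, Notch, BMP and FGF genes were lower in 15 of 26 (16 adjusted over the list alone, camera adjusted p = 0.00515, and adjusted p = 0.119 with an estimated correlation). Patterning genes were lower in 5 of 8 (5 adjusted over the list alone, camera adjusted p = 0.00838, and adjusted p = 0.119 with an estimated correlation). Matrix genes were lower in 9 of 19 (9 adjusted over the list alone, camera adjusted p = 0.0180, and adjusted p = 0.199 with an estimated correlation). Epithelial transcription factors were lower in 10 of 20 (10 adjusted over the list alone, camera adjusted p = 0.0272, and adjusted p = 0.123 with an estimated correlation). Both measured mesothelial genes were lower (2 adjusted over the list alone, camera adjusted p = 0.0110, and adjusted p = 0.119 with an estimated correlation). Nuclear and mitochondrial RNAs had a median of -0.08 without passing camera. Esr1 (0.77), Msx1 (0.20) and Epcam (0.12) were higher, and Pgr (-0.45) and Ltf (-0.84) lower. Ltf did not pass without PND12 replicate 1 (-0.70, adjusted p = 0.176), PND12 replicate 2 (-0.75, adjusted p = 0.128), PND15 replicate 1 (-0.54, adjusted p = 0.289) or PND15 replicate 2 (-0.92, adjusted p = 0.0663).

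Of 11455 genes tested, 3271 differed with Foxa2 status, 1397 higher and 1874 lower, of which 386 and 715 by at least 2-fold. Fitted at each age alone, 2486 genes differed at PND12 and 2329 at PND15. No list passed camera with an estimated correlation after adjustment. The count changed with how cells were defined, and cell numbers changed with it. With at least 2 Foxa2 UMIs, which left 13 to 40 detected cells per library, 1763 genes passed (494 higher, 1269 lower). Without Mki67 or Top2a cells, which left 12 to 37, 1671 passed (530 higher, 1141 lower). Without thinning, with 95 to 149 detected cells and more UMIs per cell, 7473 passed. A Foxa2-undetected cell can still express the gene, so the differences compare detection and not cell types.

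**Figure D4:**
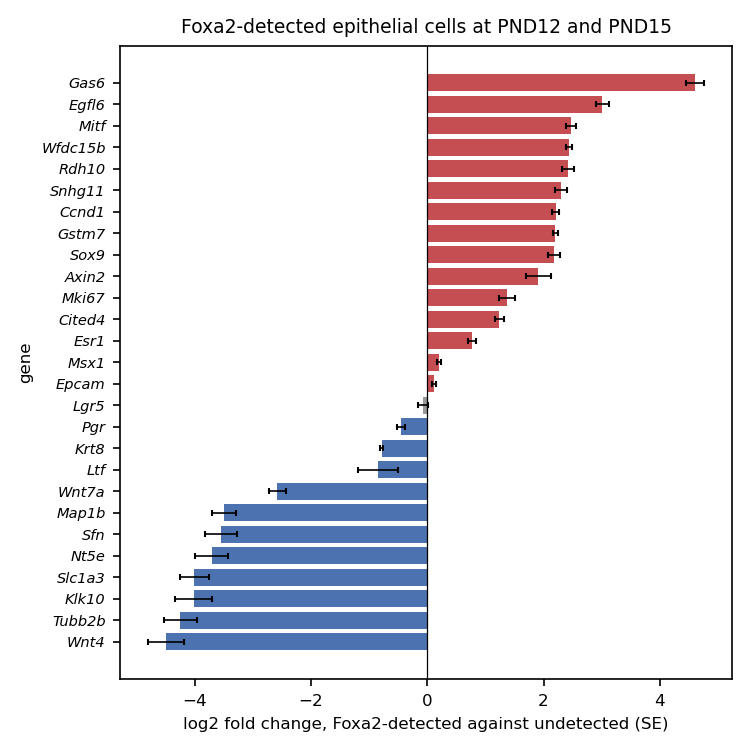
Log2 fold change of Foxa2-detected against Foxa2-undetected epithelial cells of PND12 and PND15 (horizontal axis) for named genes with the largest differences and the fixed genes (vertical axis). Bars are edgeR estimates over 6 libraries with SE, red for higher, blue for lower and grey for not called: Gas6 stands at 4.61 and Wnt4 at -4.49. For Wnt4 counting error alone is larger than the SE shown.

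The Foxa2-associated difference itself changed between PND12 and PND15 for 550 of 11455 genes (336 more positive and 214 more negative at PND15, edgeR interaction test). Aldh1a1 went from 1.17 at PND12 to 3.18 at PND15, a difference of 2.01 ± 0.20 (log2, SE, n = 3 libraries per age). Sox9 went from 1.67 to 2.69 (1.02 ± 0.19), Mitf from 1.94 to 3.00 (1.06 ± 0.15) and Rdh10 from 1.91 to 2.93 (1.02 ± 0.17). Over all epithelial cells, mostly Foxa2-undetected, Aldh1a1 changed by -2.28 and Rdh10 by -0.37 in this step, and Sox9 fell too. A wider difference so need not mean a rise in Foxa2-detected cells. Without thinning, 8.75% and 10.2% of subclusters 6 and 7, nearly all PND12 cells, held a Foxa2 UMI, against 44.1% of subcluster 11, nearly all PND15 cells. On the lower side, Sfn went from -2.22 to -4.87 (-2.65 ± 0.84). Cited4 narrowed from 1.52 to 0.95 (-0.58 ± 0.14). The count was 2505 without thinning, 250 by DESeq2's test, 151 with at least 2 Foxa2 UMIs and 149 without Mki67 or Top2a cells.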

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

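The tests of tissue handling and of UMI numbers in dividing cells were chosen after the results were seen, and so were the intervals of the ratios of medians. The Foxa2-associated difference itself differed between PND12 and PND15 for 550 genes by the interaction test (edgeR, adjusted p under 0.05). Among genes named in the report with an average log2 CPM of at least 5, it was more positive at PND15 for Aldh1a1 (2.01 ± 0.20, log2, SE), Snhg11 (1.23 ± 0.18), Mitf (1.06 ± 0.15), Sox9 (1.02 ± 0.19), Rdh10 (1.02 ± 0.17), Gstm7 (0.96 ± 0.07), Egfl6 (0.90 ± 0.19), Wfdc15b (0.49 ± 0.10), Ccnd1 (0.46 ± 0.10) and Msx1 (0.34 ± 0.07). It was more negative for Sfn (-2.65 ± 0.84), Cited4 (-0.58 ± 0.14), Junb (-0.27 ± 0.07) and Wfdc2 (-0.18 ± 0.05). The interaction does not tell whether Foxa2-detected or undetected cells moved. Real groups of 3 and 3 libraries gave 550 genes and the highest other split 0, with 1 of 10 splits as large. So few splits cannot give a share under 0.05.

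Cells outside the comparisons also carried signals. Cluster 13, led by the lymphocyte genes Cd3g, Cd52 and Cxcr6, held 12 cells at PND15, above the 3 counts that a count of 0 allows, against 1 at PND1, 1 at PND5 and 0 at PND12. Cluster 3, of 649 cells over all ages, had a median of 2369 UMIs and held 191, 116, 133 and 209 cells at the 4 ages. It followed the replicate number more than the age, with 106, 108, 120 and 111 cells in replicate 1 of the 4 ages, 79, 2, 6 and 86 in replicate 2 and 6, 6, 7 and 12 in replicate 3. No explanation was tested for either.

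Immediate early and dissociation stress genes rose together from PND12 to PND15. A difference in mitochondrial share is argued against, since among cells with 5% to 7% mitochondrial UMIs the list's median log2 change was 1.31, a ratio of 1.08 (95% interval over genes 1.03 to 1.10) to that over all cells. Fewer dividing cells are argued against as well, since without Mki67 or Top2a cells the median was 1.14 (ratio 0.942, 0.835 to 0.991). A dividing cell without such a UMI can remain, so this covers only dividing cells that were detected. Both intervals are over genes and do not measure the spread between libraries. Handling of the tissue that differed between the ages could also raise all 17 members, and cannot be told apart from age, because each age has its own libraries. Age itself stays open and untested.

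Foxa2-detected cells carried a Mki67 or Top2a UMI more often than undetected cells, at 61.5% ± 15.0 against 33.5% ± 3.96 at PND12 (SD, n = 3) and 23.5% ± 3.30 against 13.04% ± 0.732 at PND15, higher in 6 of 6 libraries (exact sign-flip test, p = 0.0312, the smallest possible). More UMIs in dividing cells are argued against as the whole cause at PND12, since after thinning the smallest difference was 16.0 points. That lay above the bound set for this age. No bound was set for PND15, where the smallest difference was 7.47 points, so the test does not decide there. Thinning did lower the mean difference, from 35.7 to 28.1 points at PND12 and from 23.9 to 10.4 at PND15, so UMI numbers could add to the difference before thinning. Doublets among cells with the most UMIs are argued against too, since without the top 5% of cells the mean difference at PND12 was 26.2 points, a mean ratio of 0.919 ± 0.0634 (SD) to that before. At PND15 it was 10.3 points. Doublets at ordinary UMI numbers were not tested. A biological difference may remain as a hypothesis, found and tested on the same data.

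Retinoid genes, among them Crabp1 and Aldh1a3, fell from PND12 to PND15. Fewer dividing cells are argued against, as far as they were detected. Without Mki67 or Top2a cells the median log2 change of the 12 falling members was -1.29 (ratio of medians 1.00, 95% interval over genes 0.869 to 1.17). A dividing cell without such a UMI can remain. A smaller share of Aldh1a1-expressing cells stays open. In cells without an Aldh1a1 UMI the other 11 members had a median of -0.65, against -1.22 over all epithelial cells (ratio 0.532, 0.476 to 1.28), although the median of the ratios per gene was 0.974 (0.611 to 1.24). The interval includes 0.5, the bound set for the test, and a cell without an Aldh1a1 UMI can still express the gene. Age stays open and untested, and a preparation that differed between ages could not be separated from it.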

How the results depend on the processing

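The limit of 20% mitochondrial UMIs, leaving out the 5% of cells with the most UMIs, leaving out each library for the lists, and the share tests within replicate number were chosen after the results were seen. The values counted here are those of called genes named in the text, 175 pairs of gene and comparison. Over all settings, 4445 of 4497 such values kept direction and call, 44 lost the call and 8 reversed. Many of these genes were named for large changes or small p-values, so these shares do not extend to all calls. Under the filter of at least 1000 genes and at most 5% mitochondrial UMIs, 107 of 136 kept both and 7 reversed. With 1 library left out, 1863 of 1872 kept both and 9 lost the call.

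The stricter filter left 35 to 62 epithelial cells per PND12 library and 2 to 12 per PND15 library, against 1437 to 2167 at PND1 and PND5, so lower counts come with fewer cells by construction. It gave 8215 genes for any age, 2428 from PND5 to PND12 (881 at least 2-fold), 819 from PND12 to PND15 (552) and 2116 from PND1 to PND15 (1612). From PND5 to PND12 Ccna2 (0.60), Ect2 (0.54), Mki67 (0.77), Axin2 (1.05), Epcam (0.24) and Krt8 (-0.0217) reversed, and Krt8 (-0.18) from PND12 to PND15. The cause was not tested. The median mitochondrial share of PND12 and PND15 barcodes, 7.19% to 7.78%, lies above this limit. The epithelial share, -0.84 points from PND1 to PND15 and not past the threshold, became -53.4 points and passed, and the step from PND5 to PND12 became -4.98. Without a cell filter the share was 9.98 points and passed, when 2329 barcodes in a cluster with a median of 77.5% mitochondrial UMIs entered the total.

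Without Mki67 or Top2a cells 5136 genes passed from PND1 to PND5 (912 at least 2-fold), with fewer cells and 13984 genes tested. Without Foxa2 cells Gas6 reversed to -0.32 from PND5 to PND12 and -0.62 from PND12 to PND15, so by construction the differences above 0 came from the Foxa2 cells. With 35 lists in each of 4 comparisons, 39 calls passed camera with the preset correlation, 12 with an estimated one and 122 passed fry, which asks a different question (whether a list moved at all). The stromal-like share of cells, PND12 to PND15, at a change of 0, became -0.0190 points at resolution 0.5 and 0.176 without a cell filter. The cause was not tested.

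For the Foxa2 comparison (3271 genes), counts not thinned gave 7473, at least 2 Foxa2 UMIs 1763, and leaving out Mki67 or Top2a cells 1671. Lgr5 reversed to 0.51 without thinning, where deeper cells are more often able to show Foxa2 by construction. The interaction (550) became 2505, 151 and 149 under the same settings and 250 by DESeq2's test, with 7679 genes tested.

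With each library left out in turn, counts were 15007 to 15180 (any age), 8624 to 9333 (PND1 to PND5), 11423 to 11944 (PND5 to PND12), 10537 to 11311 (PND12 to PND15), 13547 to 13945 (PND1 to PND15), 39 to 40 (lists), 2742 to 2966 (Foxa2) and 385 to 448 (interaction). The epithelial share changed by -2.62 to 0.323 points: it reversed without PND1 replicate 3 (0.147) or PND15 replicate 1 (0.323) and passed without PND15 replicate 3 (-2.62). The Mki67 or Top2a share from PND1 to PND5 ranged from -1.84 to 0.338 points, the latter without PND5 replicate 2. From PND1 to PND15 it ranged from -49.4 to -47.8, the Foxa2 share from 4.43 to 4.94 and the stromal-like share from -0.84 to -0.634. Nt5e in the Foxa2 comparison ranged from -6.81 to -3.39.

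The share of cells with a Foxa2 UMI changed from PND1 to PND15 by 7.36 points without thinning and 2.62 at 4000 UMIs, against 4.64, and the Mki67 or Top2a share by -43.2 and -39.3, against -48.5. A replicate block gave 15102 genes for any age, 9612, 12047, 11334 and 13824 for the 4 contrasts, and 39 lists. Correlations of same-numbered libraries had a mean of 0.158 (-0.119 to 0.458, 18 pairs), those of different numbers one of -0.0789 (-0.53 to 0.513, 36 pairs). Deviations were taken from the mean of each age, which ties the 2 sets, so their overlap decides nothing. Every pair of replicate 1 libraries correlated at 0.122 to 0.458, and 10 of 12 libraries correlated best with their own number. The labels do not pair the numbers, so the main tests left them out, and an effect of the replicate number is not excluded. With ages permuted only within replicate number, the epithelial share, -0.84 points from PND1 to PND15, passed across ages (exact F test, p = 0.0122). The Foxa2 (4.64 points, p = 0.00174), Mki67 or Top2a (p = 0.00521) and stromal-like shares (p = 0.00694) passed the same exact permutation test. The planned comparisons of stroma were not run. Depth limits Foxa2 at PND1 and PND5, with 30 and 21 UMIs, and Igf2 at PND12 and PND15, with 1 UMI at each. It also limits H19 at these later ages, with 8 and 5, and Hoxa10 and Hoxa11, with at most 1 UMI per library.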

Other observations

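No test in this part was chosen after its result was seen. Genes at least 2-fold higher in Foxa2-detected cells and with an average log2 CPM of at least 5 in that comparison could already rise before glands form. Of 52 such genes, 30 rose and 12 fell from PND1 to PND5, with a median log2 change of 0.22 (camera p = 0.000123, p = 0.245 with an estimated correlation), so the test does not decide. Genes at least 2-fold lower at the same average level did not already fall as a set: of 241, 145 rose and 69 fell, with a median of 0.20 (camera p = 8.95e-07, p = 0.197 with an estimated correlation).

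Other splits of the libraries gave fewer calls than the real groups. For any age, 1 of 100 splits gave as many as the real 15037 genes, the real one itself, and the highest other gave 9082. A random grouping of these libraries can be excluded there. Replicates may be technical, so chance differences between animals or preparations are not excluded. A split that calls many genes points to a structure of the samples, here the ages that other splits keep in part. For lists, 1 of 100 gave as many as 39, but the highest other gave 37. A grouping other than the ages thus gave nearly as many list calls, so their count does not exclude chance for the lists. For the Foxa2 comparison, 1 of 32 gave as many as 3271, and the highest other gave 550. Turning Foxa2 status in all libraries of 1 age makes this test the interaction test, which also called 550 genes. The value of 550 is thus not a level that chance alone reached. Chance is argued against there, at the smallest share that 32 splits can give. For PND1 to PND5 (9258), PND5 to PND12 (11876), PND12 to PND15 (11159) and PND1 to PND15 (13755), 1 of 10 splits gave as many and the highest other gave 0, and the splits are too few for a share under 0.05.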
